A study of Mus musculus with 24 samples.

How the data were processed

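The series measured RNA from whole pancreas of 24 C57Bl/6J mice, an inbred laboratory strain, by RNA-seq. The labels place each mouse in 1 of 8 groups of 3, defined by condition (normal circadian or circadian disrupted), sex, and an early or late time point. The early mice were taken on day 1, the late females on day 8 and the late males on day 9. The labels also give each mouse a zeitgeber time, the hours counted from lights on, of 8, 176 or 200, so all mice were taken at clock hour 8 of their day. How the rhythm was disrupted, and the day from which days were counted, are not given in the sources used here. Mice are numbered 1 to 3 within a group from their labels. The series' design text speaks of separate mice per condition and time point, so replicates are treated as separate animals.

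Per the labels' protocols, RNA was prepared with a modified column kit protocol after cervical dislocation, and libraries were made with an Illumina TruSeq protocol. The deposited table holds 1 column of RSEM expected counts per mouse for 51912 Ensembl genes, as the authors made them and without normalization. An expected count is an estimate in which reads that fit several genes are shared out among them, so it need not be whole. Per the submitters' processing notes, the tools were bcl2fastq 2.20, STAR 2.5.3a, RSEM and edgeR 3.28.0 with genome build GRCm38.p5. The notes list these names without their order or role, and neither the gene annotation nor the strand setting of the counting is given in the sources used here. Without strand information, reads from a gene and its antisense partner cannot be told apart, and near-identical copies such as the amylase and trypsin genes share reads by estimation.

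Gene symbols, coordinates and overlaps were taken from the GENCODE M21 annotation of GRCm38 by Ensembl identifier, which matched 51633 of the 51912 genes. Coordinates are given 1-based on GRCm38. All 24 columns of the table matched a mouse.

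Expected counts were rounded to whole numbers, which altered 7.97% of the deposited values by at most 0.5. Genes with low counts were removed with edgeR's filterByExpr over the 8 groups, leaving 14000 genes. Libraries were scaled with TMM factors, which ran from 0.943 to 1.12. The main test was the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 8 group means over all 24 mice and 1 shared estimate of the spread. Each contrast averaged the males and the females with equal weight, and adjusted p values are Benjamini-Hochberg values with a threshold of 0.05. Log2 fold changes are given with their standard error from this model, and levels in CPM (library-scaled counts) as mean ± SD of 6 mice. The common biological coefficient of variation was 0.130.

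The comparisons were circadian disrupted against normal circadian mice at the early and at the late time point, the difference between these effects, late against early within each condition, the difference of the condition effect between males and females at each time point, and males against females at the early time point. At the late time point sex and day of sampling go together, so that a sex difference there cannot be told apart from a day difference.

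A total of 31 gene lists, with 524 members, was fixed for the tissue and the question. Of these members 476 were among the genes tested, and 3 had no symbol in the annotation. The lists cover the clock genes that are high or low around zeitgeber time 8, glucocorticoid-responsive and temperature-responsive genes, acinar enzymes and transcription factors, the Reg family, the unfolded protein response, markers of islet, ductal, stellate, endothelial, macrophage, lymphocyte, adipocyte, red blood and smooth muscle cells, MHC class II, mitochondrially encoded genes, proliferation, immediate early genes, interferon response, inflammation, cholesterol and fatty acid synthesis, fatty acid oxidation, p53 targets, autophagy, antioxidant genes, pancreatic cancer drivers, and Xist with Y-linked genes. Each list was tested with camera of limma 3.58.1, a test of a list against the other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation between members and fry were further tests. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone.

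The clock score of a mouse is the mean log2 CPM, with a prior count of 2, of the 10 clock genes high around zeitgeber time 8 minus that of the 6 genes low at that time. Scores of 6 against 6 mice were compared by an exact two-sided permutation test over all 924 splits, with Benjamini-Hochberg adjustment over a family of 5 comparisons.

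The genes named for a comparison were every clock gene of the lists in condition and time comparisons, the 5 largest rises and the 5 largest falls among called genes, and up to 4 members with the smallest p of each list that camera called. For the largest changes a mean log2 CPM of at least 1 was required, with the same sign in males and females for condition and time comparisons, and predicted genes and pseudogenes were left out. Some genes that this rule selects are not reported here. Where no gene passed, the 3 with the smallest p are given. Genes named outside this rule are said to have been chosen after their values were seen. The groups, tests, lists, this rule and most of the other settings tried were fixed before the data were examined.

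The other settings fixed in advance were RLE and upper quartile scaling, removal of the 50 most abundant genes, DESeq2 1.42.0, limma voom with quality weights, no or a stricter low-count filter, fits on the 12 mice of a time point, a replicate block, 1 surrogate variable from sva 3.50.0, other settings of the clock score, and leaving out each mouse in turn. After the data had been seen, lymphocyte and adipocyte scores were added as covariates, and libraries rich in lymphocyte RNA were removed. Thinning of the deepest libraries and contrasts within males or within females were added too. These contrasts used the fit on all mice with its shared estimate of the spread, so no gene or list was refitted on 1 sex.

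The sequencing depth was 31325543 to 62390408 counts per mouse, of which the 50 most abundant genes took 87.4% to 89.1%, so that only the remainder of the depth bears on all other genes. The pipeline was tested on simulated counts with 200 changed genes per comparison. These were drawn from genes with a mean log2 CPM of at least 1, so recovery of less abundant genes was not tested. For the early condition effect, with 13805 genes tested, it recovered 82.1% of the 67 genes changed by 0.5 on the log2 scale and 97.0% of those changed by 1, with 9 false calls. For the condition by sex effect at the early time point, with 13811 genes tested, it recovered 13.4% of the genes changed by 0.5, 79.1% of those changed by 1 and 98.5% of those changed by 2. On simulated lists camera called 0 of 40 unchanged lists and 10 of 10 raised ones. The simulated genes were drawn independently and the lists at random, so their members were not correlated. The result therefore does not bear on lists of correlated genes. The counts of mates within a group differed by 9.03 to 58.9 in chi-square per degree of freedom, so no pair of mates agreed within sampling noise. Levels of Xist and of Y-linked genes matched the labelled sex in all 24 mice.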

Results

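RNA-seq counts were obtained from the pancreas of 24 mice, 12 males and 12 females, in 8 groups of 3. Normal circadian mice were set beside circadian disrupted mice at an early time point, day 1, and at a late one, day 8 in females and day 9 in males, always at clock hour 8. The title of the series concerns re-entrainment, the return of a tissue clock to a given light schedule, and the comparison of an early with a late time point addresses how the pancreas differs between conditions as days pass. Sequencing depth was 31325543 to 62390408 counts per mouse. The deepest libraries were disrupted early male 3 with 59811012 counts and disrupted late female 3 with 62390408, and the next deepest, normal circadian early female 2, had 42369538. Between 17680 and 19568 genes were detected per mouse.

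The counts were dominated by transcripts of acinar cells, the enzyme-secreting cells that make up most of the pancreas. The amylase gene Amy2a4 took 7.99% of all counts, Amy2a3 took 7.74% and Amy2a5 took 7.52%, followed by the chymotrypsinogen gene Ctrb1 with 6.43%. These amylase copies are near-identical, so the share of each one is uncertain. The 10 most abundant genes of a mouse took 56.6% to 60.0% of its counts, and the single most abundant gene took 7.33% to 8.97%.

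At the early time point the clock genes stood apart between the conditions, in opposite directions for the 2 lists. Dbp, a transcription factor that the clock drives directly, fell from 26.4 ± 5.96 CPM in normal circadian mice to 0.607 ± 0.232 CPM in disrupted mice (SD, 6 mice each). The log2 fold change was -5.41 ± 0.29. The period genes, which encode repressors of the clock, fell as well, with Per3 at -3.34 ± 0.17, Per2 at -2.45 ± 0.20 and Per1 at -2.35 ± 0.14. Arntl, which encodes the activator BMAL1, rose from 0.281 CPM to 6.71 ± 1.12 CPM, a log2 fold change of 4.56 ± 0.24. All 10 measured clock genes that are high around zeitgeber time 8 fell, and 5 of the 6 that are low at that time rose, with the same counts when adjusted over the list alone.

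The other members of the first list were Ciart at -2.97 ± 0.24, Bhlhe41 at -2.64 ± 0.28, Nr1d2 at -2.18 ± 0.20, Hlf at -1.96 ± 0.20, Tef at -1.93 ± 0.14 and Nr1d1, a repressor of Arntl, at -1.86 ± 0.31. In the second list Npas2, a partner of BMAL1, rose by 3.83 ± 0.42 from a low level of 0.0495 CPM to 0.742 CPM, and Nfil3 rose by 2.52 ± 0.29. Clock rose by 0.62 ± 0.14 (adjusted p = 0.017). Cry1 had a log2 fold change of 0.07 ± 0.27 (adjusted p = 0.934). The adjusted p values in edgeR's quasi-likelihood test were 1.22e-11 for Arntl, 2.48e-10 for Per3, 1.51e-09 for Per1, 4.31e-09 for Dbp, 5.98e-07 for Per2 and 0.00164 for Nr1d1. The list medians were -2.40 and 1.81, and camera called both, with adjusted p = 1.42e-08 and adjusted p = 4.56e-05 with an estimated correlation.

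**Figure D1:**
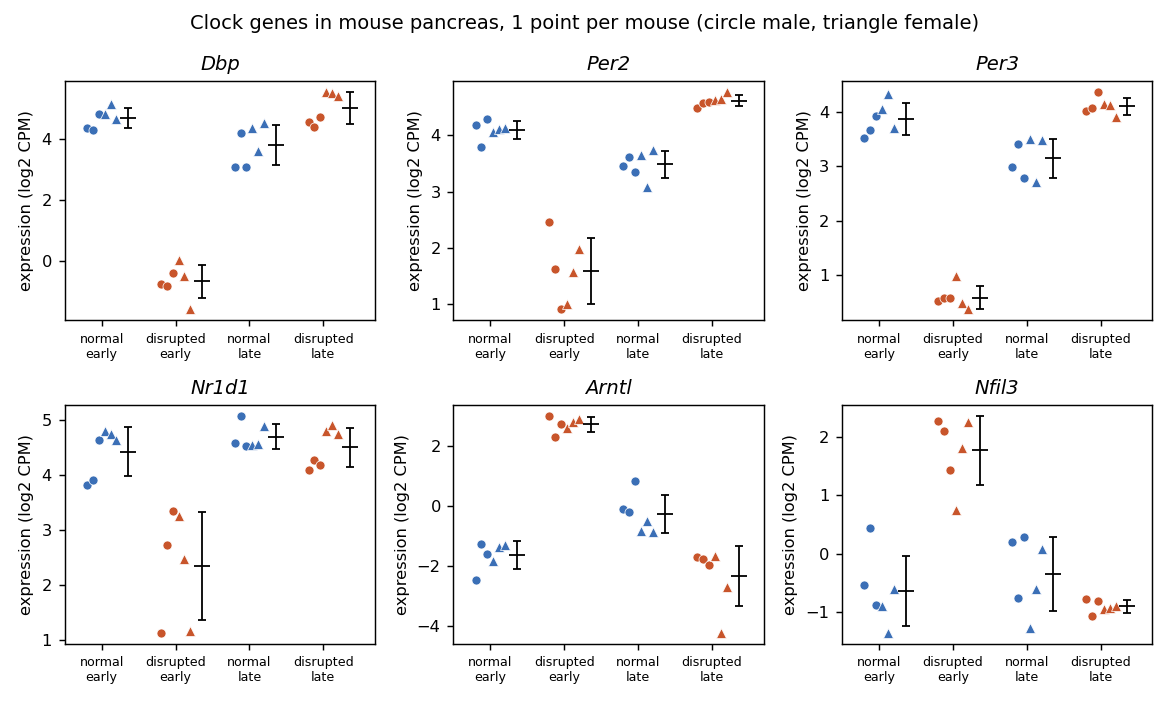
Expression (log2 CPM, y axis) of 6 clock genes in each mouse, circles for males and triangles for females, by condition and time point, with the mean and SD of 6 mice beside each group. Dbp is lowest in the disrupted early mice (0.607 CPM on average, against 26.4 CPM in normal circadian early mice), and Arntl is highest there (6.71 CPM).

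Dbp (ENSMUSG00000059824) lies on chromosome 7 at 45705088 to 45710203 on the plus strand and overlaps Sphk2 on the opposite strand. Arntl lies on chromosome 7 at 113207465 to 113314126, Per1 on chromosome 11 at 69095217 to 69109960 and Per2 on chromosome 1 at 91415982 to 91459324. Per3, on chromosome 4 at 151003652 to 151044665, overlaps Camta1 on the same strand. Nr1d1, on chromosome 11 at 98767932 to 98775333, overlaps Thra on the opposite strand, and Ciart, on chromosome 3 at 95878503 to 95882251, overlaps C920021L13Rik. These are overlaps of whole gene spans. Whether they hold shared exons was not tested and the strand setting is not known, so reads there may not be assignable to 1 gene.

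Outside the clock lists, the largest early rises were in Alb, the albumin gene, at 3.23 ± 0.46 (adjusted p = 0.000363), Trim50 at 2.38 ± 0.39 (adjusted p = 0.0015), the cell cycle inhibitor gene Cdkn1a at 1.71 ± 0.38 (adjusted p = 0.0152) and Rhobtb1 at 1.61 ± 0.17 (adjusted p = 3.25e-06). The Alb level of 8.65 ± 10.3 CPM in the disrupted mice had an SD above its mean. Usp2, which encodes a deubiquitinase, fell by 2.45 ± 0.17 on the log2 scale. These genes lie on chromosome 5 at 90460897 to 90476602 (Alb), chromosome 5 at 135353295 to 135368005 (Trim50), chromosome 17 at 29090976 to 29100727 (Cdkn1a), chromosome 10 at 69151434 to 69291791 (Rhobtb1) and chromosome 9 at 44067021 to 44095627 (Usp2).

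Camera called 7 further lists at the early time point, and none of these calls held with an estimated correlation. Of 13 glucocorticoid-responsive genes, which steroid hormone signalling switches on, 3 fell and 1 rose, with the same counts adjusted over the list alone. Their median was -0.65 (adjusted p = 0.212 with an estimated correlation), and -0.25 in males only. Klf9 fell by 0.65 ± 0.07 (adjusted p = 2.54e-06), Tsc22d3 by 0.75 ± 0.09 and Sgk1 by 0.75 ± 0.20, while Cdkn1a rose. Among 26 genes of the unfolded protein response, which relieves stress in the endoplasmic reticulum, 3 fell and 1 rose (9 and 1 adjusted over the list alone). The median was -0.20 (adjusted p = 0.496 with an estimated correlation), and -0.13 without disrupted early male 3; in males only it was -0.26, and in females only -0.03 with the call lost (camera adjusted p = 0.128). Herpud1, which takes part in the degradation of misfolded proteins, fell from 229 to 113 CPM, a log2 fold change of -1.02 ± 0.11 (adjusted p = 4.7e-06). It lies on chromosome 8 at 94386438 to 94395377. The chaperone gene Hyou1 fell by 0.41 ± 0.09. Of 16 temperature-responsive genes, mostly heat shock genes, 2 fell (5 adjusted over the list alone). The median was -0.15 (adjusted p = 0.227 with an estimated correlation), and -0.28 without disrupted early female 3. In males only it was -0.32, and in females only -0.06 with the call lost (camera adjusted p = 0.435). The 2 genes that fell were the co-chaperone genes Bag3 at -0.32 ± 0.07 and Dnajb1 at -0.47 ± 0.13, whereas Rbm3 at -0.30 did not pass (adjusted p = 0.0745).

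Of 21 cholesterol synthesis genes 6 rose (9 adjusted over the list alone), with a median of 0.27 and adjusted p = 0.212 with an estimated correlation. Hmgcs1, which encodes an early enzyme of the pathway, rose by 0.45 ± 0.08 and Stard4 by 0.77 ± 0.17. Of 15 fatty acid synthesis genes 2 rose (5 adjusted over the list alone), namely the desaturase gene Scd2 at 1.05 ± 0.22 and the elongase gene Elovl5 at 0.47 ± 0.11. The list median was 0.65 (adjusted p = 0.204 with an estimated correlation), 0.23 without disrupted early female 1, and 0.26 in males only. Among the 13 mitochondrially encoded genes 6 rose (8 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.204 with an estimated correlation). Examples were mt-Nd1 at 0.44 ± 0.08 and mt-Nd2 at 0.41 ± 0.07. Of 18 lymphocyte and lymph node genes only Lck rose, at 2.72 ± 0.68 (3 adjusted over the list alone). The list median was 1.42 (adjusted p = 0.588 with an estimated correlation), and 0.6 without disrupted early female 1. The mean log2 level of this list, centred over the mice, was 3.44 in disrupted early female 1 and 2.11 in disrupted late female 1.

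The remaining lists were not called at the early time point. Of 37 acinar enzyme genes none passed, with a median of 0.01 (camera adjusted p = 0.67). Of 9 acinar transcription factor genes Ptf1a and Gata4, named after their values were seen, rose, with a median of -0.01 (adjusted p = 0.349). In the list of 23 islet genes 1 rose, with a median of -0.09 (adjusted p = 0.491). Of 14 ductal genes 1 rose, with a median of -0.00 (adjusted p = 0.543). None passed among 15 Reg family and injury genes (median -0.07, adjusted p = 0.47), 18 stellate genes (0.08, adjusted p = 0.152) and 14 macrophage genes (0.19, adjusted p = 0.152). Nor did any among 7 MHC class II genes (0.50, adjusted p = 0.053), 6 red blood cell genes (-0.29, adjusted p = 0.782) and 5 smooth muscle genes (-0.02, adjusted p = 0.959). A single member rose among 12 endothelial genes (0.13, adjusted p = 0.053) and among 14 adipocyte genes (0.39, adjusted p = 0.47).

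Of the lists for cell states, none of the members passed for 28 proliferation genes (median -0.17, adjusted p = 0.349), 18 immediate early genes (-0.17, adjusted p = 0.707) and 9 inflammation genes (0.01, adjusted p = 0.843). The same held for 18 fatty acid oxidation genes (-0.09, adjusted p = 0.202) and 15 antioxidant genes (-0.03, adjusted p = 0.349). A single gene rose among 22 interferon response genes (0.24, adjusted p = 0.104) and among 19 pancreatic cancer driver genes (0.03, adjusted p = 0.692). Among 13 p53 targets 2 rose and 1 fell (0.21, adjusted p = 0.147), and among 17 autophagy genes 1 fell (-0.00, adjusted p = 0.349). Xist and the Y-linked genes had a median of -0.90 over 5 genes, none of which passed (adjusted p = 0.959).

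Across 14000 genes, 639 passed for the early condition effect, 293 higher and 346 lower in the disrupted mice, of which 50 and 45 changed over 2-fold. The balance turned to 346 higher and 282 lower with upper quartile scaling, 290 and 247 with 1 surrogate variable, 357 and 334 without the low-count filter, 119 and 107 with the covariates below, and 268 and 258 without the libraries rich in lymphocyte RNA. With lymphocyte and adipocyte scores as covariates, chosen after seeing the data, 226 genes passed, and the calls of Alb, Cdkn1a, Clock, Bag3, Hyou1, Scd2, Elovl5, Stard4, Lck and Sgk1 were lost. Lck is itself a member of the lymphocyte list behind these scores. Leaving out 1 mouse ended the call of Lck (adjusted p up to 0.152), Dnajb1 (up to 0.131), Sgk1 (up to 0.105) and Elovl5 (up to 0.0527 without normal circadian early male 2).

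**Figure D2:**
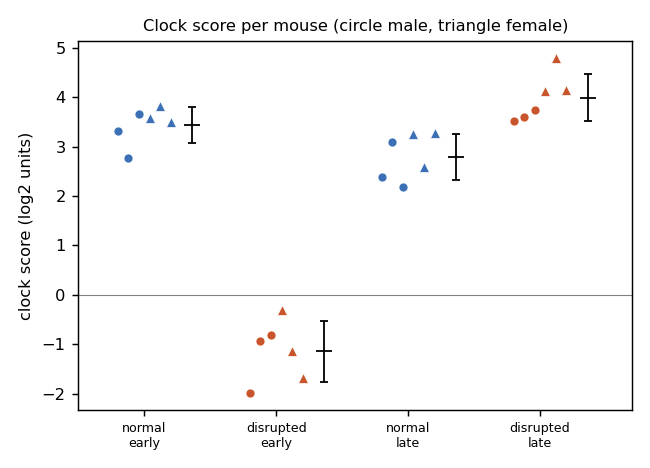
Clock score of each of the 24 mice (mean log2 CPM of 10 clock genes high around zeitgeber time 8 minus that of 6 low ones, y axis) by condition and time point, circles for males and triangles for females, with the mean and SD of 6 mice per group. Disrupted early mice lie between -1.98 and -0.31, below the normal circadian early mice at 2.77 to 3.81, and disrupted late mice lie between 3.52 and 4.79, above the normal circadian late mice at 2.19 to 3.27.

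The clock score, 1 value per mouse, was 3.44 ± 0.37 in normal circadian early mice and -1.14 ± 0.61 in disrupted early mice (SD, n = 6 each), a difference of -4.58 (exact permutation p = 0.00216, the smallest the 924 splits allow, and adjusted p = 0.00361). At the late time point it was 2.80 ± 0.47 in normal circadian and 3.99 ± 0.47 in disrupted mice, a difference of 1.19 with the same exact p and adjusted p. All 6 disrupted mice lay below all 6 normal circadian mice early and above them late. Within the normal circadian mice the late score was lower by -0.64 (exact permutation p = 0.0303, adjusted p = 0.0379). Within the disrupted mice it rose by 5.13 (exact permutation p = 0.00216, adjusted p = 0.00361). The disrupted late mice lay 0.55 above the normal circadian early mice (exact permutation p = 0.0455, adjusted p = 0.0455). Within 1 sex, 3 against 3 mice cannot give an exact p below 0.1. The early difference was -4.48 in males and -4.68 in females, and the late one 1.06 and 1.32.

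At the late time point 7 of the 10 clock genes high around zeitgeber time 8 were higher in the disrupted mice, the opposite direction to the early time point. Ciart rose by 1.71 ± 0.18 (adjusted p = 7.48e-05), Dbp by 1.14 ± 0.21 from 15.3 ± 6.48 to 34.5 ± 12.0 CPM (adjusted p = 0.00984), Per2 by 1.12 ± 0.18 from 11.3 to 24.5 CPM (adjusted p = 0.00334) and Per3 by 0.94 ± 0.14 (adjusted p = 0.0017). Bhlhe41 at 1.12 ± 0.23, Hlf at 0.96 ± 0.17 and Tef at 0.79 ± 0.13 rose too, as did Usp2 at 0.89 ± 0.15. Nr1d1 at -0.21 ± 0.29 (adjusted p = 0.785), Per1 at 0.12 ± 0.12 (adjusted p = 0.709) and Nr1d2 at 0.39 ± 0.19 (adjusted p = 0.346) did not pass. The list median was 0.95, with 7 members also adjusted over the list alone, and camera's adjusted p was 0.000847 with an estimated correlation.

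Of the clock genes low at that time only Arntl passed, falling from 0.854 to 0.176 CPM, a log2 fold change of -2.21 ± 0.32 (adjusted p = 0.000962). Npas2 at -1.22 ± 0.58 (adjusted p = 0.327), Nfil3 at -0.68 ± 0.34 (adjusted p = 0.356), Clock at -0.30 ± 0.15 (adjusted p = 0.346) and Cry1 at 1.07 ± 0.28 (adjusted p = 0.0696) did not. The list had a median of -0.49, with 1 member higher and 1 lower when adjusted over the list alone, and was not called (camera adjusted p = 0.0552).

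Of 18 measured immediate early genes, which are induced within minutes of a stimulus, 6 were lower in the late disrupted mice (12 adjusted over the list alone), with a median of -0.89 and adjusted p = 0.0184 with an estimated correlation. Fos fell by 3.21 ± 0.66 (adjusted p = 0.0178) and Egr1 by 3.72 ± 0.82 (adjusted p = 0.0338). Junb fell by 1.25 ± 0.26 (adjusted p = 0.0135) and Dusp1, a phosphatase gene, by 1.03 ± 0.16 (adjusted p = 0.00152). Egr1 lies on chromosome 18 at 34859823 to 34864984 and Dusp1 on chromosome 17 at 26505590 to 26562128. The Egr1 level in the normal circadian late mice was 67.7 ± 107 CPM. The list median was 0.07 in females (camera adjusted p = 0.643) and -1.90 in males, where 10 members fell. The direction of Dusp1 also turned in females, to 0.01. Thbs1, a matrix protein gene, fell by 1.31 ± 0.22 (adjusted p = 0.00436), and Ypel2 by 1.09 ± 0.16 (adjusted p = 0.00116).

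Camera called 5 other lists late, none of which had a member that passed over all genes or held with an estimated correlation. Lymphocyte genes had a median of 1.99 (adjusted p = 0.559 with an estimated correlation), with Ighm at 2.62 ± 0.87 (adjusted p = 0.161), and MHC class II genes a median of 0.41 (0.721). Proliferation genes had a median of -0.58 (0.559), with Cdc20 at -1.84 ± 0.48 (adjusted p = 0.0546) and 3 members lower when adjusted over the list alone. The medians of the endothelial and the unfolded protein response genes were both 0.12 (0.559 and 0.721). The lymphocyte median was 1.13 without disrupted late male 1 and 1.27 without disrupted late female 1, and the calls of all 5 lists were lost in males only, with medians of 1.13 for lymphocyte (camera adjusted p = 0.0862), 0.23 for MHC class II (0.301), -0.39 for proliferation (0.0907), 0.14 for endothelial (0.0629) and 0.04 for unfolded protein response genes (0.577). In females only the medians were 3.02, 0.47, -0.85, 0.12 and 0.25 in the same order, and only the endothelial call was lost there too (0.148). MHC class II lost its call without either of these mice (0.22 and 0.27), normal circadian late male 2 (0.27) or normal circadian late female 3 (0.28). The endothelial call was lost without normal circadian late male 1 (0.05), disrupted late male 1 or disrupted late female 2 (0.11 each), and that of the unfolded protein response without normal circadian late male 2 (0.09).

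For the late condition effect 189 genes passed, 80 higher and 109 lower in the disrupted mice, or 128 and 127 with 1 surrogate variable. Leaving out a mouse gave 71 to 261 genes, and the count moved by over 1.5 times without normal circadian late male 3 (114), normal circadian late female 2 (114), disrupted late male 1 (96), disrupted late male 3 (122) or disrupted late female 3 (71), while Junb lost its call without normal circadian late female 2 (adjusted p = 0.059), Bhlhe41 without disrupted late female 3 (adjusted p = 0.0503), Fos in 3 and Egr1 in 9 of the 24 fits (adjusted p up to 0.0659 and 0.105). With the covariates 119 genes passed, 68 higher and 51 lower, so that the balance turned, and the calls of Dbp, Bhlhe41, Egr1 and Fos were lost. Without the libraries rich in lymphocyte RNA 311 passed, and without the low-count filter 333. The fit on the 12 late mice gave 192 genes, but only 136 of the 189 were kept. It ended 6 of the 16 calls of genes picked by the naming rule.

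The difference between the late and the early condition effect followed the clock genes. All 10 genes high around zeitgeber time 8 had a positive difference that passed, led by Dbp at 6.55 ± 0.36 (adjusted p = 5.84e-09), Ciart at 4.68 ± 0.30, Per3 at 4.28 ± 0.22 and Per2 at 3.58 ± 0.27. The smallest was Nr1d1 at 1.65 ± 0.42 (adjusted p = 0.0297). Of the 6 low ones Arntl at -6.76 ± 0.40 (adjusted p = 3.28e-10), Npas2 at -5.04, Nfil3 at -3.20 and Clock at -0.92 ± 0.20 passed. Cry1 at 1.00 (adjusted p = 0.177) did not. The list medians were 3.25 and -2.06, with 10 upwards in the first list and 5 downwards and 1 upwards in the second adjusted over the list alone. Camera gave adjusted p = 1.18e-08 and 0.000612 with an estimated correlation. Usp2 at 3.34 ± 0.23 had the largest positive difference outside the lists, and Trim50 at -4.05 ± 0.58, Cdkn1a at -3.10 ± 0.57, Ypel2 at -2.41 ± 0.22 and Dtx1, a regulator of Notch signalling, at -2.09 ± 0.20 had negative ones.

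The other lists called for this difference lost their call with an estimated correlation. Unfolded protein response genes had a median of 0.32, with 5 members passing upwards (11, and 1 downwards, adjusted over the list alone; adjusted p = 0.363 with an estimated correlation). Herpud1 lay at 1.17 ± 0.15 and Hyou1 at 0.61. Cholesterol synthesis genes had a median of -0.44, with 5 members passing downwards (10 adjusted over the list alone; 0.284), such as Dhcr7 at -0.68 and Hmgcs1 at -0.52. Immediate early genes had a median of -0.92 with Fos at -3.94 and Dusp1 at -1.02 (9 downwards adjusted over the list alone; 0.256). Fatty acid synthesis genes had a median of -0.54 with 2 downwards under both adjustments (0.284), and -0.32 without disrupted early female 1. Medians were 0.18 for temperature-responsive genes (1 upwards, 4 adjusted over the list alone; 0.397) and -0.33 for p53 targets (3 downwards and 1 upwards, and 6 and 2 adjusted over the list alone; 0.298). The p53 call was lost with the replicate block (camera adjusted p = 0.0683), with a stricter low-count filter (0.477), in females only (0.156) and without disrupted early female 3 (0.0688). Mitochondrially encoded genes had a median of -0.23 and a mean of 0.14, opposite in sign (1 downwards, 6 adjusted over the list alone; 0.652). Their call held in 18 of the 24 fits without 1 mouse, but not in males only or without the 50 most abundant genes. In females only the calls of the temperature-responsive (camera adjusted p = 0.113) and immediate early genes (0.979) were lost, and in males only that of fatty acid synthesis (0.107).

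In total 668 genes passed for this difference, 324 higher and 344 lower, or 287 and 405 with upper quartile scaling, and Nr1d1 kept its call in 14 of the 24 fits without 1 mouse (adjusted p up to 0.0578). Of the 639 genes called early, 426, or 66.7%, had the opposite sign late, and Pearson's r between the early and late fold changes of these genes was -0.479 and Spearman's rho -0.454, across genes, which are not independent replicates. Over all 14000 genes tested r was 0.122, of the opposite sign. A total of 64 genes were called at both time points. Of these, 39 were higher early and lower late, where independent lists would share 2.28, and 24 were lower early and higher late, where they would share 1.98. The remaining gene was lower at both. The time points held different mice, so the comparisons shared no libraries. Without the clock lists r was -0.373.

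**Figure D3:**
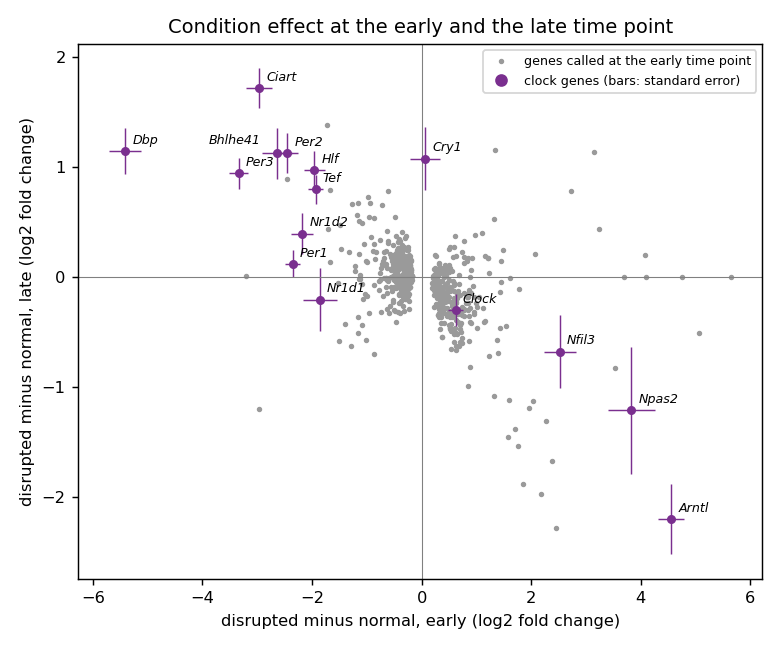
Early (x axis) and late (y axis) condition effects, as log2 fold changes of disrupted against normal circadian mice, of the 639 genes called early, with clock genes marked and bars of 1 standard error on them. Of the genes called early 426 lie in the quadrants of opposite sign, and r is -0.479 over these genes, against 0.122 over all 14000 genes tested.

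In normal circadian mice 6 of 18 immediate early genes were higher late than early (11 adjusted over the list alone), with a median of 0.82 and adjusted p = 0.0359 with an estimated correlation. The median was 1.71 in males only, whereas in females only it was -0.07 and the call was lost (camera adjusted p = 0.684). Zfp36, which encodes a protein that destabilises mRNA, rose by 1.5 ± 0.26 (adjusted p = 0.0137), Btg2 by 1.39 ± 0.24, Jund by 0.85 and Dusp1 by 0.82 (adjusted p = 0.0144 each). Among the clock genes Arntl rose by 1.49 ± 0.30 (adjusted p = 0.0172) and Per3 fell by 0.71 ± 0.14 (adjusted p = 0.0238), whereas Dbp at -0.82 (adjusted p = 0.0765) and Per2 at -0.61 (adjusted p = 0.123) did not pass. Among the largest changes Errfi1 rose by 1.53 ± 0.33 and Jun by 1.47 ± 0.33, and Id2 fell by 0.92 ± 0.17 and Pggt1b by 0.70 ± 0.13.

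Clock genes high around zeitgeber time 8 had a median of -0.57 in this comparison (1 fell, 7 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), and glucocorticoid-responsive genes a median of 0.39 (1 rose, 6 adjusted over the list alone; 0.121). Camera called 14 further lists, with adjusted p values of 0.444 to 0.618 with an estimated correlation, among them red blood cell genes at -1.66, lymphocyte genes at -1.12 and adipocyte genes at -0.47. Red blood cell genes lay at -0.91 without normal circadian early male 1, lymphocyte genes at -0.57 without normal circadian early female 3 and -0.7 without normal circadian late male 2, and glucocorticoid-responsive genes at 0.66 without normal circadian early female 3. In males only the lymphocyte median was -0.16 and the call was lost (camera adjusted p = 0.394), and glucocorticoid-responsive genes lay at 0.76 in males only and at 0.09 in females only, where their call was lost (camera adjusted p = 0.789). Of the 14 further lists each except the red blood cell genes lost its call in males only, in females only or in both. The adipocyte list kept its call in 19 of the 24 fits without 1 mouse (-0.85 to -0.26). For mitochondrially encoded genes the median of 0.15 and the mean of -0.17 had opposite signs.

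For this comparison 118 genes passed, 65 higher and 53 lower late, or 49 and 62 with upper quartile scaling, 47 and 51 with 1 surrogate variable, and 32 and 40 with the covariates. In males 312 passed and in females 0 (edgeR; 1208 at an unadjusted p under 0.05), and 7 passed for the difference between the sexes, which goes with the day. Without 1 mouse 38 to 162 genes passed, with counts of 39, 45 and 38 without normal circadian early males 1 and 2 and late male 3, 60, 52 and 71 without early females 1, 2 and 3, and 58 and 60 without late females 1 and 3. The calls of Arntl, Btg2, Dusp1 and Jund were lost without early male 1 (adjusted p 0.0512 to 0.058), that of Per3 without 4 single mice and those of Errfi1 and Jun in most such fits (adjusted p up to 0.0698, 0.115 and 0.131).

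In circadian disrupted mice both clock lists changed between the time points, with the same counts adjusted over the list alone. All 10 genes high around zeitgeber time 8 rose, with Dbp at 5.73 ± 0.29 (adjusted p = 6.69e-10), Ciart at 4.10, Per3 at 3.56, Per2 at 2.97, Per1 at 2.65 and Nr1d1 at 1.91. The list median was 2.81 (adjusted p = 6.78e-08 with an estimated correlation). Of the 6 low ones Arntl fell by 5.27 ± 0.26 (adjusted p = 2.3e-12), Npas2 by 4.36, Nfil3 by 2.86 and Clock by 0.69, with a median of -1.89 and adjusted p = 0.000569 with an estimated correlation. Cry1 at 0.26 did not pass (adjusted p = 0.569). Usp2 rose by 3.18 ± 0.17. The largest falls outside the lists were Alb at -3.56 ± 0.47, Trim50 at -2.63, Cdkn1a at -2.37 and Aqp8, a water channel gene on chromosome 7 at 123462291 to 123468004, at -1.83 ± 0.12 (adjusted p = 7.7e-11; from 9.98 to 2.75 CPM).

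Of 13 glucocorticoid-responsive genes 7 rose and 1 fell late in the disrupted mice (8 and 1 adjusted over the list alone), with a median of 0.79 and adjusted p = 0.0858 with an estimated correlation. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose by 2.80 ± 0.33 (adjusted p = 2.33e-05), Klf9 by 1.01 ± 0.07 and Tsc22d3 by 0.98, and the member that fell was Cdkn1a. Among unfolded protein response genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.16; adjusted p = 0.553 with an estimated correlation). Herpud1 rose by 1.37 ± 0.11 and Hyou1 by 0.49. Temperature-responsive genes had 5 members that rose (7 adjusted over the list alone; median 0.24; adjusted p = 0.532 with an estimated correlation), such as the chaperone genes Hsph1 at 0.91 and Hspa8 at 0.72.

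In the disrupted mice 10 of the cholesterol synthesis genes fell late (12 adjusted over the list alone; median -0.31; adjusted p = 0.553 with an estimated correlation), led by Dhcr7, the last enzyme of the pathway, at -0.67 ± 0.10 (adjusted p = 6.98e-05). Of the fatty acid synthesis genes 5 fell (8 adjusted over the list alone; median -0.65; 0.41), such as Elovl5 at -0.63 and Scd2 at -0.96; the median was -0.27 without disrupted early female 1. Stellate and fibroblast genes had 5 members that fell (8 adjusted over the list alone; median -0.24; 0.553), such as the collagen gene Col3a1 at -0.59 ± 0.13 and Postn at -0.75. Among proliferation genes 7 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.93; 0.632), with Cdc20 at -1.89 ± 0.47, Rrm2 at -0.78 and, in the other direction, the cyclin gene Ccne2 at 1.02. Interferon response genes had 3 members that fell under both adjustments (median -0.29; 0.687), such as Rsad2 at -1.14 ± 0.25, and the list lost its call without disrupted early male 2 (-0.23), disrupted early female 1 (-0.12) or disrupted late female 2 (-0.27). The total was 1948 genes, 1031 higher and 917 lower late, or 744 and 1246 with upper quartile scaling, 801 and 815 with a stricter low-count filter, 808 and 809 with 1 surrogate variable, and 768 and 788 with the covariates. In males alone 948 genes passed, and the calls were lost for stellate (-0.12, camera adjusted p = 0.458), proliferation (-0.54, 0.274), cholesterol (-0.2, 0.154), fatty acid (-0.01, 0.412), interferon (-0.16, 0.412) and unfolded protein response genes (0.08, 0.165). In females alone 1457 passed, and the call of the temperature-responsive genes was lost (0.21, camera adjusted p = 0.14).

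**Figure D4:**
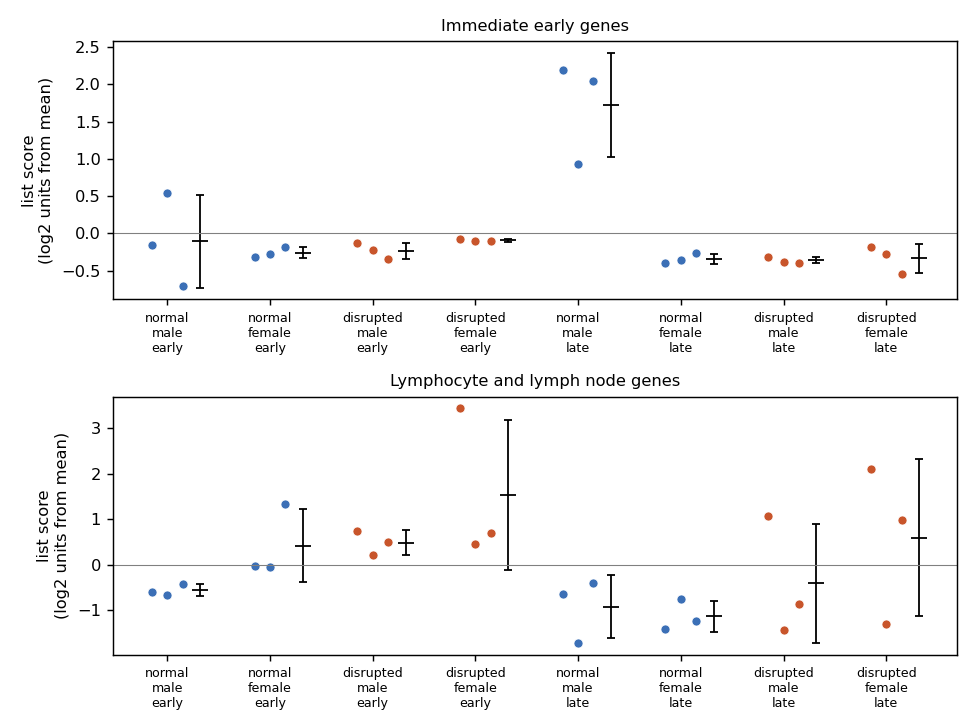
Mean log2 level of the immediate early and the lymphocyte list, centred over the mice (y axis), in each of the 24 mice by group, with the mean and SD of 3 mice. The lymphocyte list reaches 3.44 in disrupted early female 1, and the immediate early list lies between 0.93 and 2.2 in the 3 normal circadian late males and between -0.70 and 0.54 in the other 21 mice.

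At the early time point no gene differed in its condition effect between males and females in edgeR's test, nor in DESeq2 or limma voom (0 genes each), while 783 genes had an unadjusted p under 0.05. The genes with the smallest p, all of which failed (adjusted p = 0.76), were Gm45799, the splicing factor gene Hnrnpa2b1 at -0.51 ± 0.11 and the DNA repair gene Fanca at -3.38 ± 0.82. Camera called the temperature-responsive list (median -0.43), the unfolded protein response (-0.21), proliferation (-0.65) and fatty acid oxidation (0.18), with no member passing and adjusted p = 0.941 with an estimated correlation for each. All 4 calls were lost without disrupted early female 3, where the medians were -0.32, -0.08, -0.25 and 0.15 in this order, and the proliferation median was -0.98 without disrupted early female 2. The unfolded protein response also lost its call without normal circadian early male 1 (-0.12) or disrupted early male 3 (-0.14), and fatty acid oxidation without normal circadian early male 1 (0.12) or female 3 (0.16), while its median was 0.36 without normal circadian early female 1 and 0.39 without disrupted early female 1. Within the sexes 180 genes passed in males and 210 in females.

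At the late time point 4 genes differed in their condition effect between males and females, among 904 with an unadjusted p under 0.05. Dusp1 had a difference, males minus females, of -2.07 ± 0.32 (adjusted p = 0.0123) and Foxa3, a transcription factor gene of endoderm, one of -1.14 ± 0.21 (adjusted p = 0.0373). The others, 1810019D21Rik and Gm38102, had a higher effect in males, and were named after their values were seen. Of 18 immediate early genes Dusp1 passed over all genes and 15 were lower adjusted over the list alone, with a median of -2.0 and adjusted p = 0.0013 with an estimated correlation. Camera called 10 other lists, among them the glucocorticoid-responsive genes at -0.48 and the lymphocyte genes at -1.33, with adjusted p values of 0.215 to 0.884 with an estimated correlation. The lymphocyte list kept its call in 20 of the 24 fits without 1 mouse, with medians from -2.93 without disrupted late male 1 to -0.49 without disrupted late female 1, and the glucocorticoid-responsive median was -0.73 without disrupted late female 3. The mitochondrially encoded mt-Co3 had a difference of 7.58 (adjusted p = 0.821) and varied widely between mice.

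Condition effects at the late time point covered 97 genes in males and 21 in females. The count of 4 became 44 without normal circadian late male 2, 0 without normal circadian late male 3, normal circadian late female 2, disrupted late male 1 or disrupted late male 3, 1 without disrupted late female 2, and 2 without normal circadian early female 1, normal circadian late male 1, normal circadian late female 1 or disrupted late female 3. It was 36 with DESeq2, 18 with limma voom, 16 without the low-count filter, and 1 on the 12 late mice or with the lymphocyte and adipocyte covariates. With the replicate block it was 6, but only 1 of the 4 genes was kept. Dusp1 and Foxa3 lost their calls on the 12 late mice, with the covariates and with the block. In the 24 fits without 1 mouse Dusp1 kept its call in 19 and Foxa3 in 5 (adjusted p up to 0.0704 and 0.232).

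Between males and females at the early time point, Xist at -11.36 ± 0.19 (adjusted p = 2.91e-23) and the Y-linked genes Ddx3y at 10.95 ± 0.20, Eif2s3y at 9.73, Kdm5d at 9.68 and Uty at 9.16, males minus females, matched the labels. Of 37 acinar enzyme genes 7 were higher in males (10 adjusted over the list alone), with a median of 0.13 and adjusted p = 0.351 with an estimated correlation. Among them were the trypsin inhibitor gene Spink1 at 0.41 ± 0.07 (adjusted p = 0.00182) and the trypsinogen gene Prss2 at 0.29 ± 0.05 (adjusted p = 0.0028), which has near-identical copies. Of the stellate and fibroblast genes 4 were lower in males (7 adjusted over the list alone), with a median of -0.36 and adjusted p = 0.159 with an estimated correlation: the matrix metalloproteinase gene Mmp2 at -0.57 ± 0.09, Thy1 at -0.91 ± 0.16, Postn at -1.04 ± 0.18 and Lum at -0.49 ± 0.11. Igfbp5 at -1.05 ± 0.14 (adjusted p = 0.00059), Cdhr2 at -1.16 ± 0.19 and Smtnl2 at -1.16 ± 0.19 were also lower in males, and Hmcn2 was higher at 0.68 ± 0.13.

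The unfolded protein response list had a median of 0.21 in this comparison (1 member higher in males, 15 adjusted over the list alone; adjusted p = 0.351 with an estimated correlation). Lower medians in males were called for fatty acid synthesis at -0.27 (6 members adjusted over the list alone; 0.351), interferon response at -0.43 (8 members adjusted over the list alone), macrophage at -0.48, MHC class II at -0.53, lymphocyte at -1.50 and clock genes high around zeitgeber time 8 at -0.20 (0.684 each), islet genes at -0.17 (0.688) and proliferation at -0.34 (0.748), where no member passed over all genes. Without disrupted early female 1 the medians were -0.24 for interferon response and -0.28 for macrophage genes, and the calls were lost for lymphocyte (-0.51, camera adjusted p = 0.0534), MHC class II (-0.2, camera adjusted p = 0.198), clock (-0.11) and proliferation genes (-0.26). The clock list kept its call in 10 and proliferation in 19 of the 24 fits without 1 mouse, and the islet median was -0.28 without normal circadian early female 1 and -0.30 without disrupted early male 1.

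In total 125 genes passed, 56 higher and 69 lower in males, or 37 and 77 with upper quartile scaling. Of these 6 lie on X, 5 on Y and 114 elsewhere, of which 51 were higher and 63 lower in males. Without 1 mouse 55 to 220 genes passed, with 69, 73, 64 and 73 without normal circadian early males 1 and 2 and early females 2 and 3, and 55, 197 and 220 without disrupted early male 1, male 3 and female 3. Lum lost its call in several such fits (adjusted p up to 0.122). DESeq2 gave 258 genes, no low-count filter 301 and 1 surrogate variable 72.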

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

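The tests of explanations, the counts over other splits of the mice and the tests of time effects between the sexes in this part were chosen only after the results were seen, whereas the condition by time and condition by sex tests were planned.

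The condition effect differed between the time points for 668 genes, with median differences of 3.25 for the clock genes high around zeitgeber time 8 and -2.06 for those low at that time. The late clock difference, opposite to the early one, was a difference of 1.19 in clock score within the late mice (exact permutation p = 0.00216, the smallest possible), from which a shift between time points shared by both conditions cancels by the design. RNA of lymphocytes and adipocytes is argued against: with both scores as covariates the median size of the fold changes of the 8 clock genes called late was 1.11 against 1.12, all 8 kept their sign and 6 their call, while the calls of Dbp (1.14 before, 1.19 after) and Bhlhe41 (1.12 before, 1.08 after) ended at similar fold changes, with adjusted p up to 0.0608. Equal phase with a larger amplitude in the disrupted mice may be a candidate explanation, but Nr1d1 lay 1.18 below the median of the other genes of its list, 4.12 of its standard errors, and with samples at a single clock hour amplitude and phase cannot be told apart. A phase that had passed beyond that of the normal circadian mice by the late time point is a hypothesis that stays open for the same reason. The late difference also holds a change in the normal circadian mice, whose score moved by -0.64 from early to late (exact permutation p = 0.0303). Against the normal circadian early mice the disrupted late mice lay only 0.55 higher (exact permutation p = 0.0455).

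Among the late mice the condition effect differed between males and females for 4 genes, and the immediate early list had a median difference of -2.0. The 3 normal circadian late males had a mean score of 1.72 ± 0.70 (SD), each between 0.93 and 2.2, and the other 21 mice lay between -0.70 and 0.54. RNA of lymphocytes is argued against by a lymphocyte score of -0.92 in these 3 mice against 0.13 in the others, while the late disrupted males, of the same sex and day, reached at most -0.31, a value that is part of the pattern itself. Handling at collection could raise these genes together (median -2.0, adjusted p = 0.0013 with an estimated correlation), but because 1 group of 3 mice carries the pattern it cannot be told apart from an effect of condition in males. The labels give no time of death or order of collection that would separate them.

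The lymphocyte list had medians of 1.42 early and 1.99 late, disrupted against normal circadian mice, but only Lck passed early and no member late, neither call held with an estimated correlation (adjusted p = 0.588 and 0.559), and the scores of 6 against 6 mice missed the threshold (1.08, exact permutation p = 0.0671 early; 1.12, exact permutation p = 0.13 late; adjusted p = 0.169 and 0.173 over a family of 4). A lower share of acinar cells is argued against, because the highest median of the ductal, stellate and endothelial lists at either time point was 0.13. The early median was 0.6 without disrupted early female 1, and 0.55 without disrupted late female 1 as well, the other library rich in lymphocyte RNA. In males only, a contrast that these libraries do not enter, it was 1.14 and the call held (camera adjusted p = 0.00187). In females only it was 1.70. The early difference thus depends in size on disrupted early female 1 but does not rest on it alone. Without both the late median was 1.64, but it was 1.13 without disrupted late male 1, 1.27 without disrupted late female 1 alone, 1.13 in males only, where the call was lost, and 3.02 in females only. Lymphoid tissue taken along in some libraries may contribute, as all 18 measured members were highest in disrupted early female 1, and whether the remaining late difference comes from the condition was not tested further.

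In groups of 6 mice, 152 combinations of group with clock gene, list or named gene were searched for a mouse far from the rest, and 7 exceeded Dixon's limit for the gap to the nearest mouse divided by the range, where chance gives 7.6. Disrupted early female 1 stood apart for the lymphocyte list (0.834; a score of 3.44, next 0.75), MHC class II (0.821) and Per3 (0.660). Normal circadian early female 3 stood apart for the lymphocyte list (0.684). The others were disrupted late female 2 for the clock genes low around zeitgeber time 8 (0.697), normal circadian late male 1 for the endothelial list (0.760) and disrupted late female 1 for Cdkn1a (0.691).

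The effect of time differed between males and females for 7 genes in normal circadian mice and 130 in disrupted mice, where late sex and day go together.

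Other splits of the mice were drawn 80 times with the real split among them. Only 1 split, the real one, gave as many genes for the early condition effect (639, highest other 102), the late one (189, highest other 19) and their difference (668, highest other 1). The same held for time in normal circadian mice (118, highest other 55), time in disrupted mice (1948, highest other 351) and sex (125, highest other 4). A share of 1 in 80 is the smallest that these splits allow. It was not adjusted over the comparisons, so chance is unlikely for these counts but not excluded. For the difference, and for condition by sex below, the splits exchanged condition labels and so broke up the condition effect itself. These splits cannot decide whether equal effects at both time points, or in both sexes, would give such counts. For the late condition by sex effect 2 of the 80 splits gave as many (4 genes, highest other 10), and for the early one all 80 did, as the real count was 0. The early split with 52 genes exchanged the labels of 4 mice and followed the early condition effect with its sign turned (r of -0.961 across the genes called early), so the structure it points to is that effect. For the negative correlation of early and late condition effects, -0.479, 3 of the 80 splits were as large in size (highest other 0.496, in a split that moved 2 mice), whereas the share of genes with opposite signs was as extreme in 20 of the 80 splits and so could not be told from chance.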

How the results depend on the processing

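The covariates, the removal of libraries rich in lymphocyte RNA, the contrasts within 1 sex and the thinning were chosen after seeing the data. The other alternatives were planned.

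Over the planned settings other than leaving out a mouse, the calls of named genes stayed on their side of the threshold 1554 times and were lost 81 times, and those of lists stayed 531 times, were lost 55 times and reversed 2 times; when a mouse was left out, gene calls stayed 3874 times and were lost 374 times, and list calls stayed 1765 times, were lost 106 times and reversed 1 time. Over the added settings gene calls stayed 662 times, were lost 180 times and reversed 1 time, and list calls stayed 269 times, were lost 57 times and reversed 12 times. With covariates the lymphocyte and adipocyte lists were adjusted for their own scores, so their lost or turned calls there largely follow from the fit. With covariates 226 genes passed for the early condition effect, 119 for the late one, 72 for time in normal circadian mice and 1 for late condition by sex. Without the libraries rich in lymphocyte RNA the late condition effect had 311 genes. No low-count filter gave 333 for the late condition effect, 211 for time in normal circadian mice, 16 for late condition by sex and 301 for sex, where more genes were tested. DESeq2 gave 252, 36 and 258 for the last 3, and limma voom 273 and 18 for the first 2 of these; the fit on 12 mice gave 1 for late condition by sex, and 1 surrogate variable 72 for sex, and the cause was not tested. Of the 78 list calls, and apart from those whose direction turned, the stricter filter ended 26, the surrogate variable 18, the covariates 19, upper quartile scaling 4 and the replicate block 1; of the 52 that a single sex could test, 20 were lost in males and 10 in females. In males only, 180 genes passed early, 97 late, 201 for the difference, 312 for time in normal circadian and 948 in disrupted mice. These were contrasts in the fit on all mice, with its shared estimate of the spread. The clock score differences in males were -4.48 and 1.06 (exact permutation p = 0.1, the smallest possible). In females only the values were 210, 21, 285, 0 and 1457, with -4.68 and 1.32.

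Leaving out each mouse in turn gave 434 to 667 genes for the early condition effect, 71 to 261 for the late one, 525 to 717 for their difference, 38 to 162 for time in normal circadian mice, 1502 to 2053 in disrupted mice, 0 to 0 for early and 0 to 44 for late condition by sex, and 55 to 220 for sex. The clock score differences ran from -4.75 to -4.41 early and from 1.03 to 1.29 late; they were -4.89 and 1.43 with a prior count of 0.25 and -5.97 and 1.78 with 7 genes.

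For single genes the sign of the fold change turned as follows, and the cause was not tested. Cry1 early was -0.03 with limma voom, -0.05 with the replicate block, -0.17 in males only, -0.30 without disrupted early male 1 and -0.18 without disrupted early female 3, in a range up to 0.27. In males only Per1 late was -0.23, and in females only Nr1d1 late was 0.15, Dusp1 late 0.01, and for time in normal circadian mice Per1 -0.01 and Nr1d1 -0.06.

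For lists the cause was again not tested, except as stated below for covariates. The direction of a list is that of camera, which can turn without the sign of its median. Both turned for the following medians. With the surrogate variable, which followed the lymphocyte score (r of 0.937), the sex medians were 0.19 for lymphocyte and 0.12 for MHC class II genes. With covariates the lymphocyte median was -0.18 early and 0.02 for sex, and MHC class II -0.08 late and 0.03 for time in normal circadian mice. As the covariates are the scores of the lymphocyte and adipocyte lists themselves, the fit takes out most of any difference in these lists. Their values with covariates, here and below, are no independent check. In males only macrophage genes were at 0.15 and adipocyte genes at 0.38 for time in normal circadian mice, and in females only immediate early genes were at 0.07 late and at -0.07 for time in normal circadian mice. Only camera's direction turned, with a median that kept its sign or lay near 0, for islet genes in late condition by sex (0.27; 0.01 without the libraries rich in lymphocyte RNA and 0.00 without disrupted late female 1, in a range up to 0.52), for condition by time in mitochondrially encoded genes (-0.23; -0.02 in males only) and immediate early genes (-0.92; -0.12 in females only), and for fatty acid oxidation genes in time in normal circadian mice (0.15; 0.09 in females only). The sign of the median alone turned, with the call lost, for macrophage genes (0.06 for sex with the surrogate variable, 0.03 for time in normal circadian mice with covariates), and with covariates for lymphocyte (-0.09 late, 0.13 for late condition by sex), adipocyte (0.12 for time in normal circadian mice) and inflammation genes (0.01 for late condition by sex). In males only it turned for stellate and MHC class II genes (0.02 each, time in normal circadian mice).

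Mice with the same replicate number showed no clear sign of pairing. Over 12 pairs the correlation of their deviations ran from -0.253 to 0.229, above 0.1 in 5. Of 12 normal circadian mice 4, all of them males, correlated best with their own number. With so few pairs a pairing cannot be excluded. The replicate block gave 582, 176, 648, 125, 1952, 0, 6 and 144 genes for the comparisons in the order above. For the time comparisons and for sex, replicate number was instead added as a term shared by all groups. Clock score differences were -4.58 and 1.19 (exact sign-flip p = 0.0313, the smallest possible). The block ended the calls of Cdkn1a, Clock and Scd2 early, of Dusp1 and Foxa3 for late condition by sex, and of the p53 targets for condition by time. Of the called genes picked by the naming rule, 14 of 16 kept their call for the late condition effect. For condition by time it was 32 of 36, and for time in normal circadian mice 12 of 14. Depth was varied only by thinning the 2 deepest libraries, which gave 606, 182, 655, 121, 1879, 0, 4 and 136 genes; what a lower depth in all mice would limit was not tested.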

Other observations

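The late comparison of the sexes, the correlation across the clock genes and the tests of immediate early scores in this part were chosen only after the results were seen, whereas the late condition effect and the gene lists were planned.

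Among antioxidant genes, which protect against oxidative damage, Gsta3 rose in the late disrupted mice by 0.68 ± 0.11 on the log2 scale, the only member of its list to pass, and the list was not called (camera adjusted p = 0.0552). The gene was named after its value was seen. At the late time point 1312 genes differed between males and females, 769 higher and 543 lower in males, against 125 at the early time point, but the late males were taken a day after the late females.

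Across the 16 clock genes, which are not independent replicates, the early and late condition effects had an r of -0.838 and a rho of -0.809, with opposite signs for 13 genes. The comparisons shared no libraries.

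The difference of the immediate early scores between the conditions was 0.02 at the early time point (exact permutation p = 0.9) and -1.04 at the late one (exact permutation p = 0.0844; adjusted p = 0.169), neither past the threshold.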
